A study of Mus musculus with 6 samples.

How the data were processed

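Lungs of 6 mice, 2 per group, were explanted, minced and extracted with a column kit, and biotin-labelled cRNA made from 10 ug of total RNA was hybridised to Affymetrix mouse gene arrays, per the labels' protocols. The deposited values are log2 values from RMA, named in the submitters' processing notes. RMA corrects the background, equalises the distributions of the arrays and summarises the probes of each transcript cluster, so that each value depends on all arrays processed together. Software and version are not given in the sources used here. The series' value table and the authors' gene table were equal for all 35556 probe sets, and the second gave gene symbols, accessions and annotation terms.

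A chip report deposited by the authors gives quality measures per array. Its percent column, per the file headers, is the share of exon-level probe sets detected above background. Its intensity columns, per the file headers, are the mean raw brightness of perfect match and background probes. Its score columns, per the file headers, are the mean absolute residual of the RMA fit and the mean absolute relative log expression. A fraction, per the file headers, is the area under the curve that separates positive from negative control probe sets, and it lay between 0.891 and 0.909. For arrays no read depth exists, so the number of arrays sets the precision.

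Of the probe sets, 7116 controls were left out, and so were the 25% of the others with the lowest mean over the 6 arrays, which left 21330. Of the 28440 other probe sets, 25004 had 1 gene symbol, 2 had several and 3434 had none. Symbols were updated through the RefSeq gene table of GRCm38.p6, which was used for names only: 22271 matched by accession, 1412 by symbol and 557 by an older symbol, and 764 kept the name in the file. The array annotation cites an older assembly, so no coordinates are given. The 95th percentile of the negative controls lay between 7.37 and 7.69 on the log2 scale, so genes under these levels are near the background. Not every such gene is marked below.

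Groups came from the sample labels. All 6 arrays entered a limma fit with 3 group means, empirical Bayes moderation with default settings (prior degrees of freedom 3.885, residual 3) and two-sided tests, with Benjamini-Hochberg adjustment over all tested probe sets at 0.05. The p-values of single genes measure the spread between 2 mice per group, pooled over the 3 groups and moderated. The difference between the 2 LN4 lungs therefore enters every comparison. Mylpf had an SE of 1.008 in PC3 minus Control, with an SD of 0.09 in Control, 0.14 in PC3 and 2.60 in LN4 lungs. Camera with the preset correlation sets a list against other genes and does not estimate the correlation between genes across mice. Gene lists were tested with camera at a preset correlation between genes of 0.01, on 17011 genes with the brightest probe set each, adjusted over the lists. Of 40 lists, 39 had at least 5 tested genes and were tested. Camera with an estimated correlation and fry, which tests whether the genes of a list move on balance in 1 direction without comparing them with other genes, were alternatives. The estimated correlation comes from the residuals of all 6 arrays, so the difference between the 2 LN4 lungs enters it in every comparison too. The median of all changes lay between -0.0163 and 0.0156.

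The lists, the tests, the alternatives and the rule for named genes were fixed before the data were examined. The rule names Thbs1 and Psap always, the 10 most significant genes in each direction of each comparison that pass, and, where fewer pass, the genes of smallest unadjusted p with non-overlapping arrays and a change of at least 1.5-fold, as values only. It adds 4 members of each list that passes, in its direction, and 2 members of each described list that does not. The squamous and skin genes were chosen after the high squamous genes were seen, and the oesophageal list was cut from 20 genes to 16 after the values of all 20 were seen. The text gives only some of the genes that this rule picks, chosen after their values were seen. The values of 1 gene are not reported here.

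The scripts were tested on simulated arrays for the comparison of PC3 with Control, with 21330 probe sets of which 100 were changed by 1 and 100 by 2 on the log2 scale. With the spread of all 6 arrays, 5 and 78 were recovered and 5 unchanged probe sets were called. With the spread of the 2 Control arrays, 99 and 100 were recovered and 12 unchanged ones were called. In a second simulation of the same comparison, with 2000 genes, unchanged lists of 20 genes with a true correlation of 0.3 passed an unadjusted p of 0.05 in 41.5% of 200 runs of camera with the preset correlation, 1.5% with an estimated one and 3% of runs of fry. Lists of 20 uncorrelated genes shifted by 1 residual SD passed in 99%, 72.5% and 76.5%. Fits used R 4.3.3 with limma 3.58.1, and figures Python 3.11.15 with matplotlib 3.10.9.

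Alternatives were no filter or a filter of 50% on dim probe sets, a trend and robust prior, median centring, quantile normalization, array weights, the authors' table, fits of only the 4 arrays compared, an adjusted p of 0.1, a fold minimum, and each array left out in turn. Added after seeing the data were the detection pairs as a block, the fit without the 2 arrays with squamous genes, and the fit without probe sets raised in LN4 replicate 3.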

Results

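Gene expression was measured in whole lungs of 6 C57BL/6 mice, aged 8 weeks, that had received daily intraperitoneal injections of 100 uL of medium for 7 days. The Control group (replicates 2 and 4) received plain RPMI culture medium. The PC3 group (replicates 4 and 5) received medium conditioned by PC3 cells, a human prostate cancer line. The LN4 group (replicates 1 and 3) received medium conditioned by PC3M-LN4 cells, a more metastatic derivative of that line. Each of the 3 groups held 2 mice, and each mouse gave 1 array, so the number of arrays limits the precision of every value. From what is known of the study, it set lungs that favour metastasis against lungs that resist it, with an interest in thrombospondin-1, encoded by Thbs1, and prosaposin, encoded by Psap. Values are log2 RMA values, so a difference of 1 is a doubling, and changes are given with the standard error (SE) of the limma fit.

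The arrays differed in ways the groups do not account for. The share of detected probe sets was 38.4% in Control replicate 2, 39.8% in PC3 replicate 4 and 35.4% in LN4 replicate 1, called here the low-detection arrays. It was 48.4%, 50.9% and 46.1% in the high-detection arrays, Control replicate 4, PC3 replicate 5 and LN4 replicate 3. The gap within a group lay between 10.1 and 11.1 percentage points. LN4 replicate 3 stood apart: its Pearson correlation with the other arrays across genes lay between 0.918 and 0.933, whereas the remaining pairs of arrays lay between 0.961 and 0.99. Across genes, which are not independent replicates, the first principal component held 57.8% of the variance and set this array at 76.0, with the others between -20.1 and -7.00.

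In LN4 replicate 3, 553 tested probe sets lay over 2-fold above every other array. They included keratins and cornified envelope genes of stratified squamous epithelium, named here after their values were seen. Krt13 was at 13.61, against 5.16 and 4.63 in the Control lungs and 5.09 in LN4 replicate 1. Krt4 was at 13.52 against 4.44 in LN4 replicate 1, and Sprr3 at 13.20 against 4.89. Skeletal muscle genes were high in the same array: Acta1, skeletal muscle actin, was at 12.04 against 6.87 in LN4 replicate 1, and Ckm, muscle creatine kinase, at 11.12 against 6.47. PC3 replicate 4 also held Krt13 at 10.63, Krt4 at 10.03 and Sprr3 at 9.09, against 5.06, 3.97 and 4.63 in PC3 replicate 5, while its Acta1 was at 6.50. Krt10, a keratin of skin, lay between 5.89 and 6.32 in all 6 lungs.

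**Figure D1:**
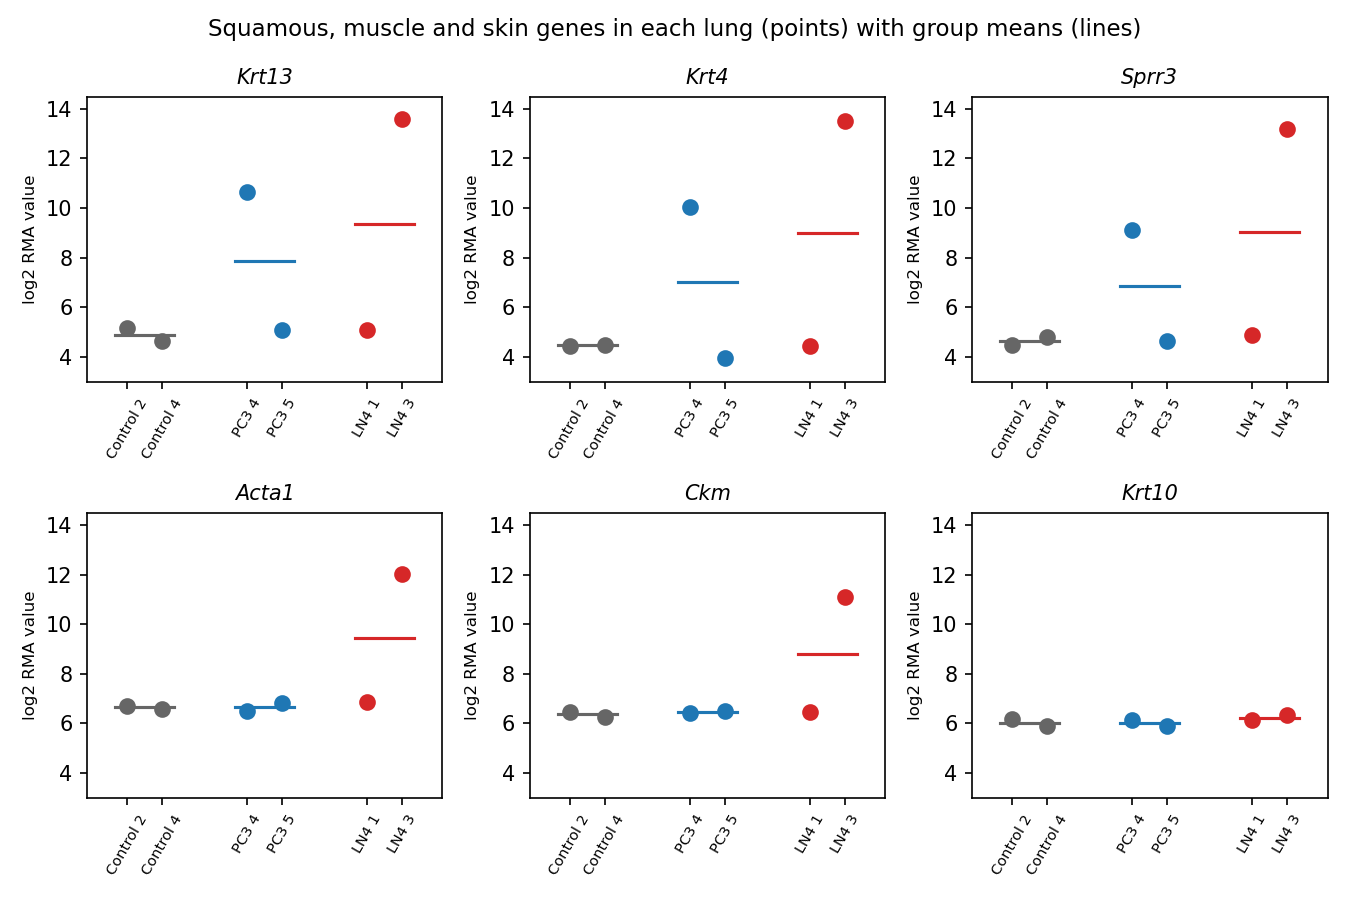
Log2 RMA values (y axis) of 3 squamous epithelial genes, 2 skeletal muscle genes and the skin keratin Krt10 in each of the 6 lungs (points), with group means as lines. LN4 replicate 3 holds both kinds of gene (Krt13 13.61, Acta1 12.04), PC3 replicate 4 holds the squamous genes without the muscle genes (Krt13 10.63, Acta1 6.50), and Krt10 stays between 5.89 and 6.32.

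The first comparison asked what PC3-conditioned medium changed in the lung. Genes of mesothelial cells, which line the pleural surface, were higher in PC3 lungs. 12 of the 13 measured members had higher means, with a median change of 0.70 (adjusted p = 0.667 with an estimated correlation). Lrrn4 was at 8.54 ± 0.46 against 7.50 ± 0.13 (SD, n = 2), with 1 Control array under the 95th percentile of the negative controls, and Upk3b, a uroplakin of mesothelium, at 10.20 ± 0.52 against 9.22 ± 0.09. Gpm6a differed by 0.94 (SE 0.24) and Aldh1a2, an enzyme of retinoic acid synthesis, by 0.94 (SE 0.24). 5 members passed when adjusted over the list alone and 0 over all genes tested. The median change of the list was 1.24 between the low-detection arrays, whose PC3 lung held squamous genes, and 0.29 between the high-detection arrays. It was 0.42 without LN4 replicate 3 and PC3 replicate 4, the arrays with squamous genes.

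Ribosomal protein genes were lower in PC3 lungs, with 18 of 20 members lower and a median change of -0.29 (adjusted p = 0.667 with an estimated correlation). That median was -0.30 between the low-detection and -0.20 between the high-detection arrays. Rps24 differed by -0.60 (SE 0.26) and Rpl7 by -0.47 (SE 0.21), and neither passed over the list alone. Among genes outside the lists, the Y RNA Rny1 was at 4.82 ± 0.02 against 6.15 ± 0.18, Snord1c, a small nucleolar RNA, at 4.55 ± 0.09 against 5.42 ± 0.18, and Rps21 at 8.33 ± 0.20 against 9.22 ± 0.17 (SD, n = 2).

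Lymphocyte genes were lower as groups. T cell and NK cell markers had 15 of 20 members lower and a median change of -0.22, and B cell and plasma cell genes 11 of 15 and -0.24. With an estimated correlation the adjusted p was 0.667 for both lists and for platelet genes, and 0.889 for MHC class I genes. Cd79a, a signalling chain of the B cell receptor, was at 7.02 ± 0.08 in PC3 lungs and 7.61 ± 0.05 in Control lungs (SD, n = 2), and the cytotoxic granule gene Gzma differed by -0.71 (SE 0.30). The B cell median was -0.01 between the low-detection and -0.31 between the high-detection arrays, and that of T and NK cells -0.20 and -0.18. Platelet and megakaryocyte genes had a median change of -0.20, from -0.12 to -0.29 in the same order, -0.40 without PC3 replicate 4 and -0.09 without Control replicate 2. Pf4, platelet factor 4, differed by -0.57 (SE 0.20). MHC class I genes had a median of -0.10, with -0.26 and 0.02 within the detection pairs.

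Among the lists that follow, the adjusted p with an estimated correlation was 0.667 for the immediate early, glucocorticoid response and acute phase lists, 0.8115 for proliferation genes and 0.889 for lipid and xenobiotic metabolism genes. Immediate early genes, which respond within minutes to stimulation, had 15 of 25 members lower and a median change of -0.14 (-0.05 and -0.11 within the detection pairs). Egr1 differed by -0.88 (SE 0.22), Ier3 by -0.61 (SE 0.18) and Nr4a1 by -0.64 (SE 0.21). Glucocorticoid response genes had 14 of 16 members higher and a median change of 0.18 (0.37 and 0.09). Fkbp5, a co-chaperone of the glucocorticoid receptor, was at 8.11 ± 0.09 against 7.36 ± 0.21, and Zbtb16 at 9.08 ± 0.11 against 8.29 ± 0.03 (SD, n = 2). Acute phase and innate defence genes had 14 of 17 members higher and a median of 0.32 (0.33 and 0.16). The complement genes Cfb and C3 differed by 0.87 (SE 0.22) and 0.65 (SE 0.22), and Lbp, which binds bacterial lipopolysaccharide, by 0.60 (SE 0.18). Lipid and xenobiotic metabolism genes had 26 of 29 members higher and a median of 0.19 (0.22 and 0.11). Fmo2, a lung monooxygenase, differed by 0.50 (SE 0.21). Proliferation genes had 19 of 22 higher and a median of 0.22 (0.11 and 0.29), with Rrm2, near the background, at 0.35 (SE 0.17).

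These 11 of the 39 tested lists passed camera with a preset correlation between genes, 5 higher and 6 lower. None passed with an estimated correlation or with fry, and 1 of the 39 had an unadjusted p under 0.05 with each. The shared adjusted p of 0.667 is a tie of the adjustment. For the lists with this value, camera with an estimated correlation gave unadjusted p from 0.0386 (immediate early genes) to 0.137 (platelet genes). Without PC3 replicate 4 the calls of T and NK cell markers (-0.21), acute phase genes (0.29) and MHC class I genes (0.04) ended, and without PC3 replicate 5 those of lipid metabolism (0.09), glucocorticoid response (0.22), proliferation (0.14) and platelet genes (0.04). Without Control replicate 2 those of lipid metabolism (0.06), glucocorticoid response (0.06) and MHC class I genes ended, and without Control replicate 4 those of B cell (-0.04), proliferation (0.21) and MHC class I genes. Thbs1 was at 9.76 ± 0.26 in PC3 lungs and 9.69 ± 0.27 in Control lungs, and Psap at 12.32 ± 0.07 and 12.14 ± 0.14 (SD, n = 2). The Thbs1 difference of 0.07 (SE 0.23) lay within the spread between replicates. It was -0.12 without Control replicate 2 and -0.11 without PC3 replicate 5. Thrombospondins and their receptors, a list that also holds Psap and Adamts1, did not pass. Its median change was 0.12 and its adjusted p 0.396 by camera. Neutrophil markers did not pass either (adjusted p = 0.169, tested as lower while their median was 0.01), with S100a8 at 6.67 ± 0.50 and 7.94 ± 0.84 and S100a9 at 6.88 ± 0.31 and 8.16 ± 0.77 in PC3 and Control lungs. Across all 21330 probe sets, 0 passed an adjusted p of 0.05 in the limma fit, where 477 had an unadjusted p under 0.05, 112 higher and 365 lower, and chance alone gives 1066.5. The pooled spread behind these p-values includes the difference between the 2 LN4 lungs.

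**Figure D2:**
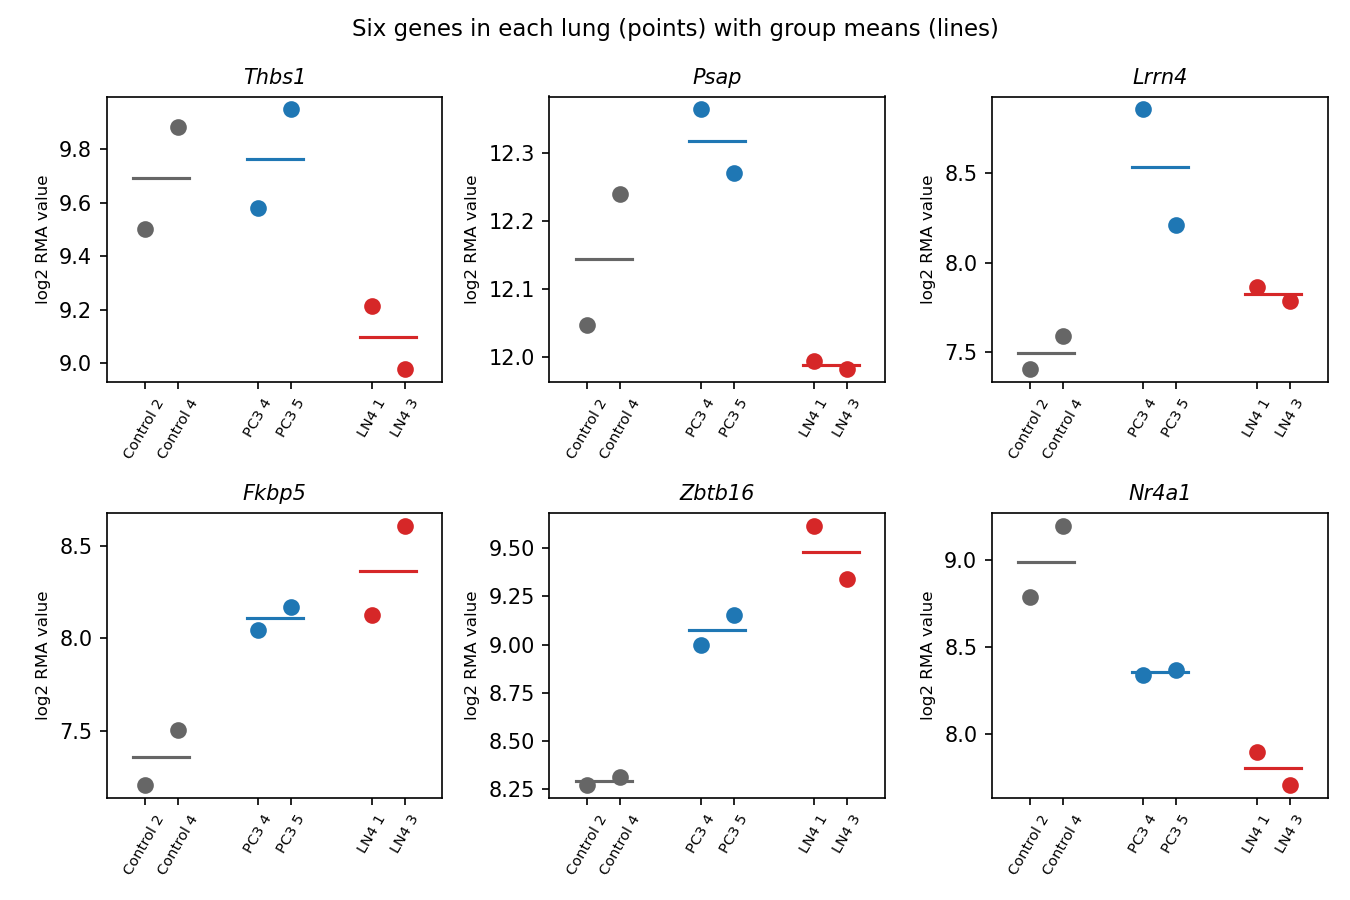
Log2 RMA values (y axis, a range of its own in each panel) of Thbs1, Psap and 4 further genes in each of the 6 lungs (points), with group means as lines. Thbs1 lies at 9.21 and 8.98 in the LN4 lungs and between 9.50 and 9.95 in the other 4, and none of the 6 genes passed over all genes tested.

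The second comparison asked what PC3M-LN4-conditioned medium changed. B cell and plasma cell genes were lower, with 12 of 15 members lower and a median change of -0.44 (adjusted p = 0.4725 with an estimated correlation). Fcer2a, the low-affinity IgE receptor of B cells, was at 5.18 ± 0.01 in LN4 lungs and 6.14 ± 0.05 in Control lungs (SD, n = 2), all under the 95th percentile of the negative controls. Cd79a differed by -0.70 (SE 0.21). T cell and NK cell markers had 18 of 20 members lower and a median of -0.27 (adjusted p = 0.504 with an estimated correlation), with Nkg7 at -0.65 (SE 0.25). The B cell median was -0.17 between the low-detection and -0.67 between the high-detection arrays, and that of T and NK cells -0.15 and -0.43. The high-detection LN4 array is replicate 3, with the squamous and muscle genes, and without it the medians were -0.37 and -0.16.

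Glucocorticoid response genes were higher, with 11 of 16 members higher and a median change of 0.27 (0.31 and 0.10 within the detection pairs). The adjusted p with an estimated correlation was 0.4725 for this list and for the immediate early and TGF-beta lists. Zbtb16 was at 9.48 ± 0.20 against 8.29 ± 0.03 and Fkbp5 at 8.37 ± 0.34 against 7.36 ± 0.21 (SD, n = 2), the first 2.27-fold higher and the second with both Control arrays under the 95th percentile of the negative controls. Pdk4, which restrains glucose oxidation, was at 7.17 ± 0.34 against 6.06 ± 0.14, both means under the 95th percentile of the negative controls. 3 members passed as higher and 1 as lower when adjusted over the list alone, and 0 over all genes tested. Immediate early genes had 16 of 25 members lower and a median of -0.17 (-0.12 and -0.14). Nr4a1 was at 7.80 ± 0.13 against 8.99 ± 0.29, 2.28-fold lower, and passed over the list alone. Dusp1, a phosphatase of MAP kinases that also stands in the glucocorticoid list, differed by -0.74 (SE 0.20). TGF-beta response genes had 16 of 20 members lower and a median of -0.18 (-0.09 and -0.30). Ccn1, a secreted matrix protein, was at 9.35 ± 0.07 against 10.39 ± 0.05 and was the member that passed over the list alone.

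Thrombospondins and their receptors, a list that also holds Psap and Adamts1, were lower. Of its 10 members 7 were lower, Psap and Adamts1 among them, and its median change was -0.25 (-0.20 and -0.36). Its adjusted p was 0.4725 with an estimated correlation, as for cardiomyocyte genes, and it was 0.504 for the alveolar cell and alveolar macrophage lists. Thbs1 was at 9.10 ± 0.17 in LN4 lungs and 9.69 ± 0.27 in Control lungs (SD, n = 2), a difference of -0.59 (SE 0.23), and both LN4 arrays lay below both Control arrays. Of all tested probe sets 28.89% had non-overlapping arrays in this comparison, in either direction, where chance gives 33.33%. The order of the arrays alone is therefore no evidence. Adamts1, a protease with thrombospondin repeats, differed by -0.85 (SE 0.22). Psap differed by -0.15 (SE 0.17). Alveolar type 1 and type 2 cell genes had 19 of 20 members lower and a median of -0.33 (-0.06 and -0.55). Scd1, a fatty acid desaturase, differed by -0.98 (SE 0.28), and Abca3, the transporter of surfactant lipid, by -0.58 (SE 0.20). Without LN4 replicate 3 the median of this list was -0.12. Alveolar macrophage markers had a median of -0.15 (-0.04 and -0.25), with Ear2 at -0.45 (SE 0.19). Cardiomyocyte genes had a median of 0.20, with 0.28 and -0.14 within the detection pairs. Without LN4 replicate 3 the median was 0.33, and without the probe sets raised in that array the call ended at 0.01. The leading members Csrp3 and Ttn are also expressed in skeletal muscle, and Ttn was at 9.83 in LN4 replicate 3 against 6.83 in replicate 1. Within the detection pairs the list median was positive only in the pair with LN4 replicate 1, and without replicate 3 it rests on that array alone. Nppa, near the background, went the other way from Ttn, at 7.53 in replicate 1 and 5.90 in replicate 3.

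The other lists that passed did so only with LN4 replicate 3 in the fit, and their adjusted p with an estimated correlation was 0.504, or 0.585 for the airway and MHC class I lists. Skeletal muscle genes had a median change of 2.31, with 0.002 between the low-detection and 4.63 between the high-detection arrays. Hypoxia and glycolysis genes had a median of 0.29, led by Egln3 at 9.80 in replicate 3 and 5.45 in replicate 1, and proliferation genes one of 0.18. Dendritic cell and MHC class II genes had a median of -0.28, endothelial cell genes -0.27, fibroblast and smooth muscle genes -0.22, MHC class I genes -0.21, extracellular matrix and collagen genes -0.19, angiogenesis regulators -0.19 and premetastatic niche genes -0.19. Among them, Kdr, a receptor of VEGF on endothelium, differed by -0.50 (SE 0.20), Pdgfrb, a receptor of pericytes, by -0.73 (SE 0.20), and Postn, a matrix protein, by -0.70 (SE 0.28). Club and ciliated airway cell genes had a median of -0.42 with both arrays and 0.16 without replicate 3, where they passed in the other direction. The secretoglobin gene Scgb3a2 was at 11.17 in replicate 3 and 12.55 in replicate 1.

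In this comparison 20 of 39 lists passed camera with a preset correlation, 5 higher and 15 lower. With an estimated correlation none passed, and 1 had an unadjusted p under 0.05. With fry none passed, and 5 had one. Without LN4 replicate 3, 9 of the 20 still passed in the same direction. Without PC3 replicate 4 as well, 7 did, and the calls of thrombospondin (adjusted p = 0.0563, median -0.26) and alveolar macrophage genes (0.0665, -0.12) ended. Without LN4 replicate 1, which leaves the array with squamous and muscle genes, the calls of thrombospondin (-0.24), cardiomyocyte (-0.13), immediate early (-0.23), alveolar macrophage (-0.10) and premetastatic niche genes (-0.25) ended. Without Control replicate 4 those of alveolar macrophage (-0.06) and premetastatic niche genes (-0.09) ended, and without Control replicate 2 those of matrix (-0.13) and MHC class I genes (-0.20). The call of premetastatic niche genes also ended without either PC3 array, at an unmoved median. In the limma fit 0 of 21330 probe sets passed, with a smallest adjusted p of 0.9997, and 437 had an unadjusted p under 0.05, 181 higher and 256 lower.

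The third comparison set the 2 conditioned media against each other. Thbs1 was at 9.10 ± 0.17 in LN4 lungs and 9.76 ± 0.26 in PC3 lungs (SD, n = 2), 1.59-fold lower, with both LN4 arrays below both PC3 arrays. Non-overlapping arrays, in either direction, were found here for 29.49% of all tested probe sets, where chance gives 33.33%. The Thbs1 difference of -0.67 (SE 0.23) did not pass over all genes (adjusted p = 0.842 in the limma fit). Thrombospondins and their receptors, with Psap and Adamts1, were lower as a list. Its median change was -0.39, with -0.33 between the low-detection and -0.44 between the high-detection arrays. Its adjusted p was 0.658 with an estimated correlation. 7 of the 10 members were lower and 0 passed over the list alone. Thbs3 differed by -0.75 (SE 0.18) and Cd36, a receptor of thrombospondin-1, by -0.51 (SE 0.20). Psap was at 11.99 ± 0.01 against 12.32 ± 0.07, a difference of -0.33 (SE 0.17). The call of this list ended without LN4 replicate 3, at an adjusted p of 0.0531 with the median at -0.36, and without PC3 replicate 4, at 0.0605 with the median at -0.42.

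Lipid and xenobiotic metabolism genes were lower in LN4 than in PC3 lungs, with 23 of 29 members lower and a median change of -0.35 (-0.34 and -0.40 within the detection pairs). With an estimated correlation the adjusted p was 0.663 for this list and for the alveolar cell and adipocyte lists, and 0.658 for the acute phase, mesothelial, ribosomal protein and platelet lists. Scd1 was at 10.93 ± 0.16 against 11.94 ± 0.23 (SD, n = 2), 2.01-fold lower, and Gclc, which makes glutathione, differed by -0.75 (SE 0.20). Alveolar type 1 and type 2 cell genes had 19 of 20 members lower and a median of -0.35 (-0.16 and -0.65), with Abca3 at -0.65 (SE 0.20). Acute phase genes had 13 of 17 lower and a median of -0.44 (-0.39 and -0.60), with Lbp at -0.78 (SE 0.18) and C3 at -0.65 (SE 0.22). Mesothelial cell genes had 12 of 13 lower and a median of -0.67 (-0.88 and -0.22), with Gpm6a at -0.73 (SE 0.24). Ribosomal protein genes had 19 of 20 higher and a median of 0.31 (0.33 and 0.43), with Rps3 at 0.50 (SE 0.17). Platelet genes had 10 of 12 higher and a median of 0.23 (0.23 and 0.38), with Ppbp at 0.57 (SE 0.18). Adipocyte genes had a median of 0.28, with 0.42 and -0.06 within the detection pairs, and Car3, a carbonic anhydrase of fat and muscle, was at 9.64 ± 0.85 against 7.97 ± 0.26. Without LN4 replicate 3 these 7 lists still passed, the acute phase genes barely, at an adjusted p of 0.05, while the median of the alveolar list moved to -0.15 and that of the adipocyte list to 0.59. Without PC3 replicate 4 as well, 4 did, and the calls of the acute phase (-0.18), mesothelial (-0.39) and ribosomal protein lists (0.07) ended. Without LN4 replicate 1 the calls of the lipid (-0.33), platelet (0.26) and adipocyte lists (-0.08) ended, and without PC3 replicate 5 those of the platelet (0.08) and adipocyte lists (0.05). Without PC3 replicate 4 alone further calls of this comparison ended that are not named here.

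The remaining calls ended without LN4 replicate 3, and their adjusted p with an estimated correlation lay between 0.658 and 0.715. Skeletal muscle genes had a median of 2.36, with -0.001 between the low-detection and 4.62 between the high-detection arrays, and hypoxia and glycolysis genes one of 0.13, with -0.27 and 0.52. Club and ciliated airway cell genes had a median of -0.39 (-0.05 and -0.98) and extracellular matrix and collagen genes one of -0.28 (-0.08 and -0.45), with fibronectin, Fn1, at 9.47 ± 0.06 against 10.27 ± 0.13 (SD, n = 2). Alveolar macrophage markers had a median of -0.28 (-0.29 and -0.16), TGF-beta response genes -0.21 (-0.18 and -0.30), and fibroblast and smooth muscle genes -0.23 (-0.03 and -0.44). Interferon response genes had -0.24 (0.14 and -0.58), and dendritic cell and MHC class II genes -0.19 (0.11 and -0.37). With the detection pairs as a block the calls of the fibroblast, hypoxia and interferon lists ended, at adjusted p of 0.0793, 0.0798 and 0.0865.

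**Figure D3:**
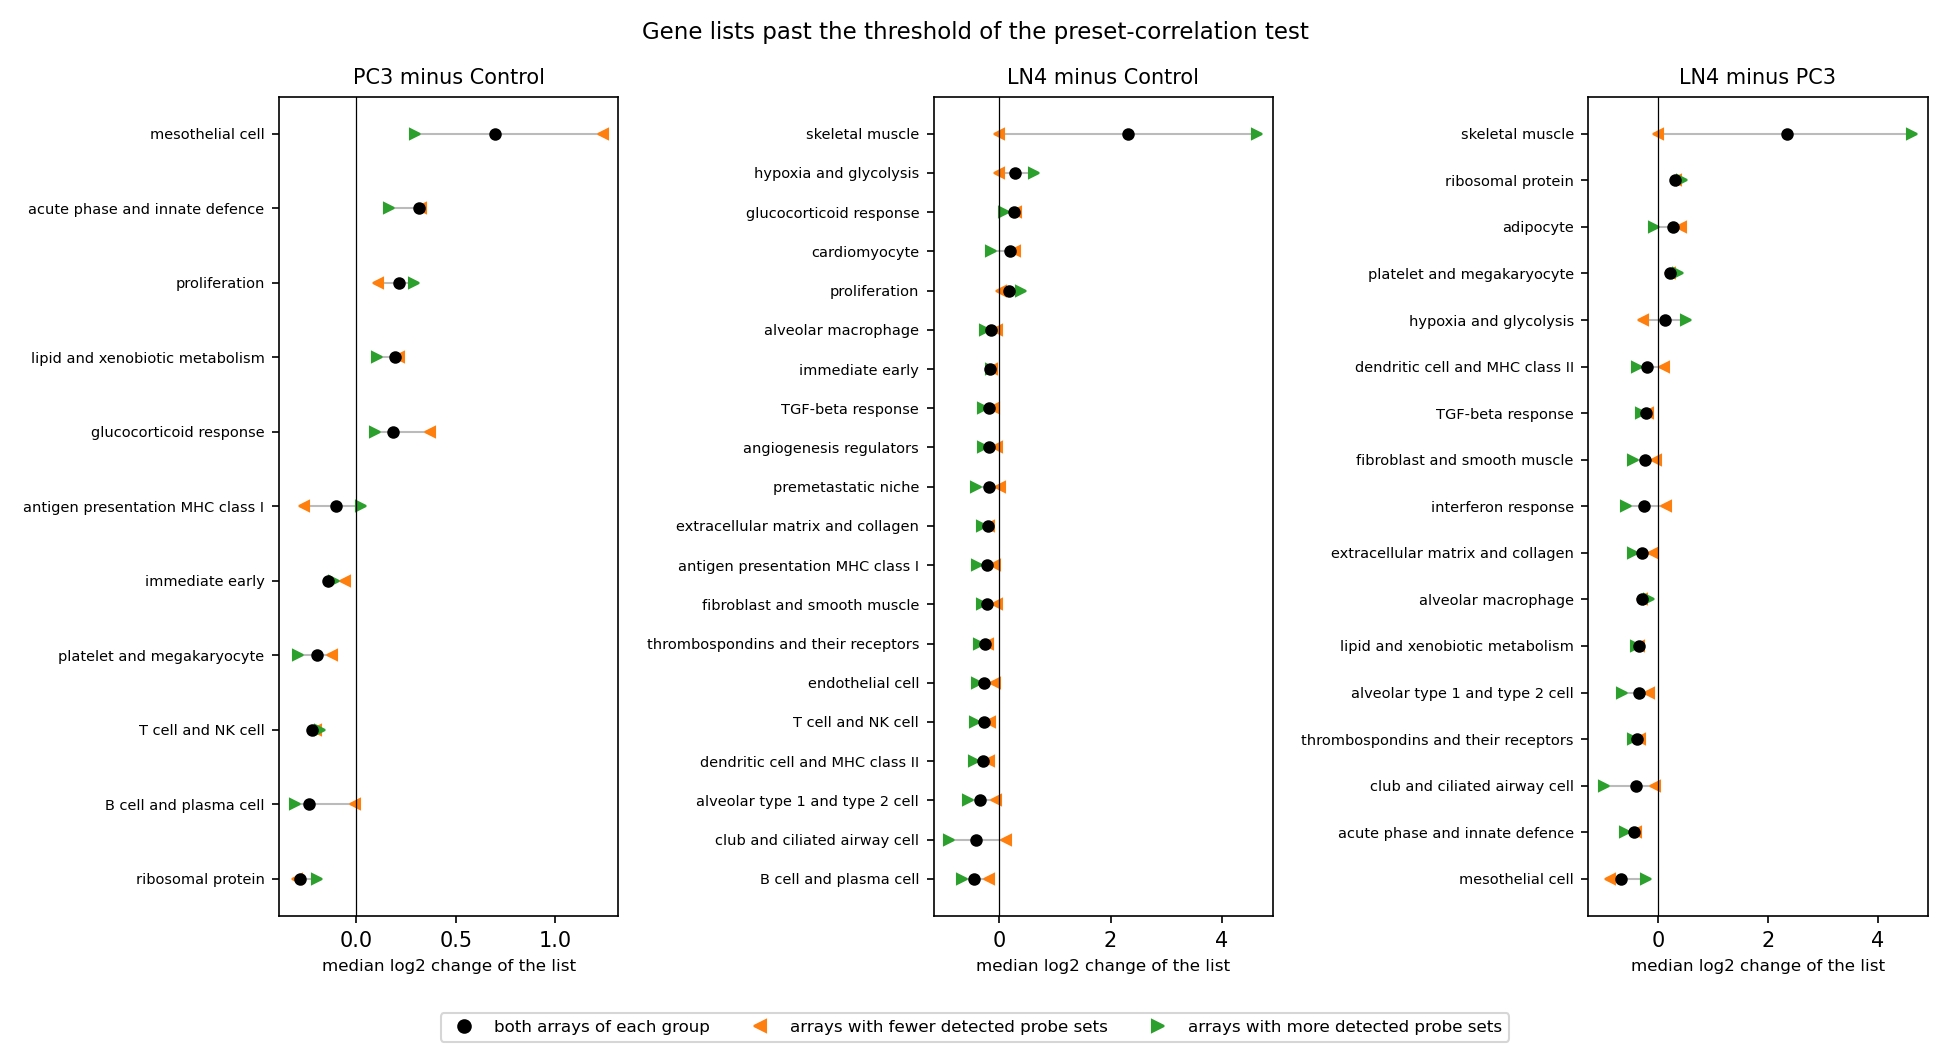
Median log2 change (x axis) of each gene list that passed the preset-correlation test, in 3 panels for the 3 comparisons, with both arrays of each group (black circles), the low-detection arrays (orange) and the high-detection arrays (green). Skeletal muscle genes lie at 4.63 and 0.002 within the detection pairs of LN4 against Control, and mesothelial genes at 0.29 and 1.24 in PC3 against Control.

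In all, 17 of 39 lists passed camera with a preset correlation, 5 higher and 12 lower in LN4 lungs. With an estimated correlation none passed, and 1 had an unadjusted p under 0.05. With fry none passed, and 2 had one. Over single probe sets 0 passed in the limma fit, where 1094 had an unadjusted p under 0.05, 470 higher and 624 lower, and chance gives 1066.5. In the F test for any difference among the 3 groups 0 passed, and 534 had an unadjusted p under 0.05. The smallest two-sided p that an exact permutation test of 2 against 2 arrays allows is 0.333, so no single gene could pass such a test.

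The last comparison asked whether both media moved the same genes. The covariance across genes of the log2 changes of PC3 and LN4 lungs against Control was 0.0268, where unchanged groups that share the 2 Control arrays gave 0.0396 in simulation with the spread of all arrays. The spread of the Control arrays alone gives 0.0154. The observed value lay 0.0128 under the first and 0.0115 over the second. The first gives the Control arrays a spread that includes LN4 replicate 3, which is too large for them. The SD of the difference across genes was 0.690 in the LN4 pair and 0.248 in the Control pair. The second is the closer reference but rests on 1 pair of arrays. The excess over it was not kept without LN4 replicate 3 or without PC3 replicate 4, so a shared effect of the media is left open. The correlation was 0.304 across genes, which are not independent replicates, and 0.4996 in simulation. Without LN4 replicate 3 the covariance was 8.288e-05, without PC3 replicate 4 it was 0.00145, and without both, which hold squamous genes, it was -0.0333. Splitting the controls left 1 array for each medium and gave -0.00497 or 0.0279, depending on which Control array served which medium.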

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

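All explanations weighed here were tested after the values they concern had been seen. In the chip report, which the comparisons do not use, both arrays of a medium group lay above both Control arrays in 2 measures of fit. The mean absolute residual of the RMA fit was 0.2111 in LN4 lungs against 0.1652 in Control lungs. It was higher in the low-detection array of every group, with 0.2415 in LN4 replicate 1 and 0.1806 in LN4 replicate 3. LN4 replicate 1, against which replicate 3 is often set here, thus had the highest residual of all arrays. Its mean perfect match brightness of 289.6 lay under its background mean of 311.6, as in no other array. The mean relative log expression was 0.3546 in PC3 lungs and 0.412 in LN4 lungs against 0.2778.

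The squamous and striated muscle genes of LN4 replicate 3 may come from oesophageal tissue left on the lung piece, which stays an open hypothesis. A list of 16 genes of oesophageal epithelium had a median 3.832 above the mean of the Control arrays and LN4 replicate 1, with Krt13 at 13.61 and Krt4 at 13.52, 2 of the 16 above the 95th percentile of the negative controls in Control lungs and 1 in another list. This restates the observation, because the 16 were picked after the values of 20 genes had been seen and 4 were left out, Ivl, Krt16 and Barx1, which had not risen, and Anxa8 (0.17, -0.01, -0.29 and 1.00), and all 20 had a median of 2.97. Skin is argued against by 12 skin and hair genes, 0 of them above the negative controls in Control lungs, with a median of -0.1385. A squamous change of lung epithelium alone would leave 16 skeletal muscle genes, likewise 0, with a median of 4.116, unexplained. Their rise is part of the pattern itself, so it is no separate test. What remains open is whether Krt13, Krt4 and Sprr3 in PC3 replicate 4 have the same source, since that array lacks the muscle genes. Only these 3 of the 16 lay over 2-fold above PC3 replicate 5. The median difference between these arrays was 0.65 for the 16 and 0.40 for the 12 skin and hair genes, so 0.65 alone does not show a broad squamous rise. An effect of the media was not tested.

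The lower ribosomal protein genes of PC3 lungs were weighed against a lower yield of short RNAs and the detection split. The split is argued against by falls in both detection pairs, the smaller a median of -0.1963 over the fixed list. Over all 447 ribosomal protein probe sets the medians were -0.40 between the low-detection and -0.13 between the high-detection arrays, so the size of the fall differed. Each group holds an array of each kind, so the split was balanced over the groups from the start and this test adds little. A lower yield of short RNAs cannot be told apart from an effect of the medium: 254 small nuclear and nucleolar RNA probe sets had a median of -0.1633, with a bootstrap interval of -0.21 to -0.12 that spans the bound set for it. A wider definition tried afterwards, with Y and further U RNAs that include the low Rny1, gave -0.18 and would have met that bound, so the outcome depends on the definition. An effect of PC3 medium stays open and untested.

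Fkbp5 and Zbtb16, targets of the glucocorticoid receptor, were higher in both media groups than in Control lungs. The arrays without squamous genes held the difference too: over both genes, PC3 replicate 5 and LN4 replicate 1 lay at least 0.6179 above the higher Control array. Both genes were picked for small p, and the rule that named Zbtb16 required both PC3 arrays above both Control arrays. Part of this was therefore built in, and it argues against oesophageal tissue only weakly. A large difference in time of day at sampling is argued against by 8 clock output genes, whose larger median absolute change was 0.211. Of these, 7 lay above the negative controls, and all 8 stand in other lists. That measure ignores direction, so a modest difference stays open. In every array of either medium Arntl, near the background, was higher (6.06 to 6.28) than in Control lungs (5.92 and 6.04). Dbp (9.60 to 9.79 against 9.90 and 9.93) and Nr1d1 (9.98 to 10.16 against 10.17 and 10.53) were lower in every such array, and the others were mixed. Both comparisons share the 2 Control arrays, so low values in these alone could give the same pattern, and stress hormone levels, an effect of tumour media or cage differences stay open as hypotheses.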

How the results depend on the processing

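Detection as a block, the fit without both arrays with squamous genes and the fit without probe sets raised in LN4 replicate 3 were chosen after seeing the data. No paired analysis was possible because the groups share at most 1 replicate number. Counts of genes were 0 in all 3 comparisons and the F test with no filter, the 50% filter, a trend and robust prior, centring, quantile normalization, array weights, the authors' table, an adjusted p of 0.1, a fold minimum and the detection block, and in the 3 comparisons in fits of the 4 arrays compared. With single arrays left out they ranged from 0 to 646 for the F test, from 0 to 853 for LN4 minus Control and from 0 to 715 for LN4 minus PC3, the highest each without LN4 replicate 1, which leaves replicate 3 with its squamous and muscle genes. Without both arrays with squamous genes they were 1622 for the F test, 514 for PC3 minus Control, 200 for LN4 minus Control and 2593 for LN4 minus PC3. In such fits a lone array is assumed to vary like the other groups, and in the last the spread comes from the Control pair alone, with PC3 replicate 5 high and LN4 replicate 1 low in detection, so these counts do not separate medium from array. Thbs1 in LN4 minus PC3 passed there (-0.73, adjusted p = 0.0355) and in none of its other alternatives, where the adjusted p ranged from 0.198 to 0.9995.

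The number of lists past the threshold was 0 in each comparison with an estimated correlation and 0 with fry. With single arrays left out it ranged from 7 to 12 for PC3 minus Control (7 without PC3 replicate 5), from 12 to 22 for LN4 minus Control (12 without LN4 replicate 3) and from 7 to 18 for LN4 minus PC3 (7 without LN4 replicate 3, 9 without PC3 replicate 4). Without both arrays with squamous genes it was 13 for PC3 minus Control (9 of the 11 kept), 10 for LN4 minus Control (7 of 20) and 4 for LN4 minus PC3 (4 of 17). With centring or array weights all 48 calls were the same, with the detection block 45, without a filter 47, with quantile normalization 44 and with the 50% filter 41.

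Without both arrays, LN4 minus Control reversed for hypoxia genes (-0.0728), club and ciliated genes (0.161) and MHC class I genes (0.00977), for Hk2 (-0.0494), Hspa1a (-0.011) and Smpx (-0.0121). LN4 minus PC3 reversed there for club and ciliated genes (0.0555) and hypoxia genes (-0.0478). With single arrays left out, LN4 minus Control ranged from -0.0728 to 0.583 for hypoxia genes, -0.906 to 0.161 for club and ciliated genes, -0.419 to 0.00977 for MHC class I genes, -0.0494 to 1.25 for Hk2, -0.011 to 2.14 for Hspa1a and -0.0121 to 3.99 for Smpx. LN4 minus PC3 ranged from -0.159 to 0.554 for hypoxia genes, -0.35 to 0.0223 for MHC class II genes, -0.412 to -0.0139 for interferon genes (whose test turned while the median stayed negative), -0.272 to 0.0142 for Kit and -0.471 to 0.0104 for Cd1d1. PC3 minus Control ranged from -0.118 to 0.263 for Thbs1, -1.06 to 0.0012 for Il1b and -0.0453 to 0.293 for Myh2. The covariance ranged from 8.288e-05 to 0.0535 and was -0.00497 with Control replicate 2 for PC3 and replicate 4 for LN4, and -0.0333 without both arrays. The causes of these changes were not tested.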

Other observations

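The annotation terms of biological processes were tested after the lists had been seen, over 834 terms of 10 to 200 genes. In LN4 lungs 36 terms passed camera with the preset correlation, but none with an estimated correlation (adjusted p = 0.995). With the preset one, 4 also passed in the same direction without both arrays with squamous genes. These were B cell receptor signaling (13 genes, median change -0.41), phagocytosis with engulfment (11 genes, -0.23), cell migration (60 genes, -0.16) and muscle contraction (22 genes, 0.23). In PC3 lungs 6 terms passed, among them the electron transport chain (94 genes, median -0.08) and B cell activation (21 genes, -0.17), both lower, and amino acid transport (35 genes, 0.20), higher. Their adjusted p with an estimated correlation was 0.999. Without both arrays with squamous genes 1 of the 6 still passed, regulation of Rab GTPase activity (36 genes, median 0.15, adjusted p = 0.00761), though without LN4 replicate 3 alone its adjusted p was 0.0534. The same value ended the call of amino acid transport, as did the detection block (0.0746). Between LN4 and PC3 lungs 28 terms passed, none with an estimated correlation (adjusted p = 0.9998), and 0 of the 28 also passed in the same direction without both arrays.

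Probe sets of 4 gene families, chosen after the lists had been seen, were summarised in PC3 lungs against Control without an enrichment test, with bootstrap intervals over probe sets, which are not independent. The 55 Nduf probe sets of respiratory complex I had a median change of -0.24 (-0.32 to -0.14) and 46 had lower means. The 44 cytochrome oxidase and Uqcr probe sets had -0.29 (-0.46 to -0.16) and 39 had lower means. Mitochondrial ribosomal proteins (89 probe sets) had -0.10 (-0.17 to -0.04), and proteasome subunits (56) -0.06 (-0.20 to 0.02), which spans 0. In LN4 lungs the Nduf median was 0.05 and the cytochrome oxidase median 0.01.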
